A study of Mus musculus with 33 samples.

How the data were processed

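Spleen cells of BALB/c mice were cultured with a CpG oligodeoxynucleotide (ODN), with a control ODN that lacks CpG motifs, or in medium alone, and RNA was taken after 2, 4 or 8 h. Each ODN was an equimolar mix of a pair of sequences, given at 1 uM per the labels. Total RNA was extracted with TRIzol, reverse-transcribed from an oligo(dT) primer with aminoallyl nucleotides and coupled to Cy5. Every array also carried Cy3-labelled Universal Mouse Reference RNA, a pool from several mouse tissues and cell types that served as the common reference. The series holds 33 such arrays, with 4 per group at 2 h and 4 h and 3 per group at 8 h. No dye was swapped, so a gene-specific dye effect is part of every ratio and drops out of differences between groups.

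The deposited table gives 1 log ratio per probe and array, taken here as log2 of Cy5 over Cy3, and the authors' steps of background correction, spot filtering and within-array normalization are not given in the sources used here. The log base is not stated either. Base 2 was taken from the range of the values, -6.51 to 8.54, and every log2 difference printed rests on that reading. The direction, spleen cells over reference, follows from the dyes per the labels. In the values, the median ratio was 2.63 for 15 B cell markers and 1.68 for 16 T cell markers, against -0.52 for 22 markers of non-splenic tissues in the reference. Array medians lay between -0.085 and 0.024. The table has 16720 probes, of which 11303 were measured on at least 1 array, 5417 on none and 5203 on all 33. The number of probes with a value per array, from 7908 to 11129, is the only measure of depth in the table, and the number of arrays per group limits the precision.

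Probes were named from the platform annotation, which can be old. It pairs 14656 probes with 1 gene symbol and 6 with several, while 2058 probes, 1047 of them measured, have none. The Entrez identifiers of 14361 probes were found in a current RefSeq gene table, which changed 0 symbols. Probes with several symbols or none stayed out of the gene tests. Leaving out the unnamed probes was decided after the table had been seen, and the tests were run with them too. A gene with several probes was represented by the probe with the fewest missing values, which applied to 511 genes. This gave 9672 genes with values, 4612 of them on all arrays. At 8 h, 495 genes had several probes tested against the control ODN and 42 of these were called; 7 had another probe of opposite sign, in 1 of them, Rnf181, at an unadjusted p below 0.05.

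Each array was centred on its median. A model with 1 mean per group, over all 9 groups, was fitted to each gene with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. Every adjusted p for a gene in the text comes from this limma fit unless another setting is named, and errors beside log2 differences of single genes are standard errors (SE) from it. Errors beside the mean difference of a set of genes are SE from the spread of the arrays' own means. A gene entered a comparison where each compared group had at least 2 measured arrays. The group-means fit with missing values was written out in full and checked against lmFit. The prior degrees of freedom were 5.75 and the median residual SD was 0.350 on the log2 scale. The comparisons were CpG ODN against control ODN, CpG ODN against medium and control ODN against medium at each time, the change of the CpG ODN against control ODN difference from 2 h to 4 h and to 8 h, and medium at 8 h against medium at 2 h.

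The comparisons, the tests, the gene lists, the rule for the genes named and most alternative settings were fixed before the data were examined. The lists cover cytokines, chemokines, TLR and NF-kB signalling, immediate early genes and MAPK feedback, interferon response, lymphocyte activation and costimulation, MHC class II antigen presentation, cytokine signalling and its suppressors, cell cycle and DNA replication, ribosome biogenesis and MYC-driven growth, apoptosis and survival, heat shock and the unfolded protein response, and markers of B cells, T cells, NK cells, monocytes and macrophages, dendritic cells, neutrophils and myeloid precursors, erythroid cells, platelets and megakaryocytes, and non-splenic tissues of the reference. Some genes stand in more than 1 list. Lists with at least 5 tested genes were tested with limma's cameraPR at a preset inter-gene correlation of 0.01, adjusted over all lists and the 9 comparisons within a time, and again with the correlation estimated from the residuals of genes measured on all arrays.

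The genes named per time were the 8 largest rises and 6 largest falls against the control ODN among genes called against both controls with the same sign and measured on every array of that time. To these came up to 3 called members of each functional list (or the member with the smallest p where none was called), up to 2 called markers per cell type, and Tlr9, Il6, Tnf, Il12b, Il10, Ifng, Ccl3, Ccl4, Cxcl10, Cd69, Cd86, Myc, Socs3 and Nfkbia. Where fewer than 3 genes were called against both controls, genes called against the control ODN alone were to be used. For control ODN against medium, for the changes between times and for medium over time, the 5 largest rises and 5 largest falls among called genes were taken. Some genes that the rule names are covered by group summaries only, and a gene outside the rule is marked as chosen after its values were seen.

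The fit was tested on simulated data, in which every group had the gene's mean over all arrays, normal noise had the gene's residual spread, and missing values stayed missing. Among genes measured on all arrays, 100 were changed by 1 and 100 by 2 on the log2 scale in the CpG ODN group of each time. At a size of 1 it recovered 66% at 2 h (9302 genes), 72% at 4 h (9630 genes) and 46% at 8 h (9494 genes), and at a size of 2 it recovered 96%, 98% and 94%. False calls made up 6.90%, 4.49% and 7.28% of all calls. Alternatives were no centring, quantile normalization, stricter and looser filters on missing values, the mean of a gene's probes, the repeat number as a block, only the compared groups in the fit, robust moderation, array weights, the early arrays as a batch term or left out, and leaving out each array in turn. Testing the unnamed probes too was added after seeing the data. The early arrays are the 4 with database numbers below 70000 in the labels, namely CpG ODN 2 h replicate 1, control ODN 2 h replicates 1 and 2, and medium 4 h replicate 1. They are too few for a comparison among themselves.

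Replicates are the repeats that the labels number; the series text speaks of independent experiments but does not tie arrays to them. The repeat numbers paired the arrays in part. Deviations from the group means of same-numbered arrays correlated across genes above 0.1 in 21 of 33 pairs (median 0.36). Of the 33, 18 correlated best with their own number. The main fit has no term for this pairing. Where the pairs correlate positively, its p-values can be too large. A low share of small p-values then does not show that genes were unchanged. For control ODN against medium at 8 h the pairs correlated at 0.653, 0.484 and 0.645, and the fit with the repeat number as a block is given beside that result.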

Results

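The data are log2 ratios of spleen cell RNA over a common reference RNA, from 33 arrays. CpG ODN are short synthetic DNAs with unmethylated CpG motifs, which Toll-like receptor 9 (Tlr9) recognises in B cells and dendritic cells. The control ODN was included to set apart what any ODN does, whatever its sequence, and medium alone to set apart the effect of handling and culture. There were 4 arrays per group at 2 h and at 4 h and 3 per group at 8 h. The mean number of measured probes per array ranged from 9695 ± 1314 (SD, n = 4) for the control ODN at 2 h to 10883 ± 147 (SD, n = 3) for the control ODN at 8 h. Correlations between arrays over all probes ran from 0.664 to 0.961. A difference of 1 on the log2 scale is a doubling, where the unstated base is 2.

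After 2 h, CpG ODN raised a small set of inflammatory genes over the control ODN. Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, rose by 2.35 ± 0.32 (SE, log2, n = 4 against 4) and the cytokine Tnf by 2.28 ± 0.24. Nfkbiz, a nuclear regulator of NF-kB target genes, rose by 1.91 ± 0.19, and the chemokine Ccl3 by 1.61 ± 0.22. The limma adjusted p of these genes ran from 3.70e-07 for Nfkbiz to 1.10e-04 for Ccl3. Ptgs2 lay at -3.95 ± 0.11 (SD, n = 4) with the control ODN and at -1.60 ± 0.69 with CpG ODN, so that its ratio to the reference stayed below 0 even after the rise. Il12b, which encodes a subunit of interleukin 12, differed by 1.34 ± 0.30 (n = 4 against 3) but did not pass the test (adjusted p = 0.202), though it passed with quantile normalization (1.58). All 4 called genes lay above the control ODN mean on 4 of 4 CpG ODN arrays. The calls came from these same arrays, so this is no separate support.

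These 4 genes were all the calls among 9302 genes tested at 2 h. An unadjusted p below 0.05 was found for 213 genes, a smaller share than the 0.05 that unchanged genes give on average, though the fit leaves out the pairing of repeats. The same 4 genes were called against medium, where Tnf rose by 2.49 ± 0.24 and Ptgs2 by 2.31 ± 0.32. Of 9211 genes tested against both controls, independent lists of this length would share 0.00174, and simulated unchanged groups, which leave out the effects, gave 0 at most. Both comparisons share the CpG ODN arrays, which can add to the overlap. With 2 of these arrays set against the control ODN and the other 2 against medium, a test added after the data were seen, 3 to 4 genes were shared over 6 divisions. Against medium, the count was 11 without medium replicate 1, 7 with the repeat number as a block within each time, 8 with quantile normalization and 122 with array weights. The difference with CpG ODN was -0.30 ± 0.36 for Tlr9, 0.09 ± 0.21 for Ccl4 (n = 3 against 3), 0.04 ± 0.31 for Cd86 and 0.47 ± 0.20 for Il6, none past the test.

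Among the gene lists at 2 h, 1 of 30 cytokines rose, 2 when adjusted over the list alone, and the list was higher as a group (adjusted p = 1.67e-05, and 6.03e-04 with an estimated correlation). Of 25 chemokines 1 rose, 2 when adjusted over the list alone (list adjusted p = 0.0069, and adjusted p = 0.448 with an estimated correlation). Of 30 immediate early genes 1 rose, 2 when adjusted over the list alone (list adjusted p = 4.57e-04, and adjusted p = 0.266 with an estimated correlation). Cell cycle genes were higher as a group with 0 of 49 called by limma, and 0 at an unadjusted p below 0.05 (median 0.15, list adjusted p = 0.0013, and adjusted p = 0.265 with an estimated correlation). The 17 genes of MHC class II presentation had a median of -0.10 and the 15 B cell markers of -0.34, with 0 members called by limma in either list and 4 and 3 at an unadjusted p below 0.05. Their list adjusted p was 0.0081 and 0.033, and adjusted p = 0.088 and 0.597 with an estimated correlation. The 41 interferon response genes had a median of -0.10 and 0 calls by limma, with 0 at an unadjusted p below 0.05 (list adjusted p = 0.377). Of 33 genes of TLR and NF-kB signalling 1 rose, also 1 when adjusted over the list alone, with a median of -0.06 against a mean of 0.04 (list adjusted p = 0.106). Against medium, chemokines and cell cycle genes did not pass at 2 h (list adjusted p = 0.101 and 0.117). There 4 lists passed, and of these only cytokines with an estimated correlation (adjusted p = 0.0435).

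After 4 h, inflammatory genes were again higher with CpG ODN, and interferon-inducible genes were called too. Tnf exceeded the control ODN by 2.96 ± 0.24 (SE, log2, n = 4 against 4), Il12b by 2.85 ± 0.28, Ccl3 by 2.33 ± 0.22 and Nfkbiz by 2.27 ± 0.19. Batf, a transcription factor of lymphocyte activation, rose by 1.95 ± 0.29, Swap70, which acts in B cell activation and migration, by 1.74 ± 0.31, and Ptgs2 by 1.74 ± 0.32. Ifit1, an antiviral gene induced by interferon, rose by 1.71 ± 0.20, the interferon-inducible chemokine Cxcl10 by 1.37 ± 0.23 and Il6 by 1.18 ± 0.20. The difference of Ifit1 between CpG ODN and control ODN was larger at 4 h than at 2 h by 1.69 ± 0.29 (limma adjusted p = 0.020), and Ifit1 was the 1 gene among 9260 called for such a change. Leaving out 1 array gave 0 genes for CpG ODN 2 h replicates 1 and 2, control ODN 2 h replicates 1 and 3, control ODN 4 h replicates 2 and 4, and CpG ODN 4 h replicate 1, and 2 genes for control ODN 2 h replicate 2 and CpG ODN 4 h replicate 2. The count was also 0 without the early arrays, with genes measured on every array and with a block shared across times, and 11 with array weights. An unadjusted p below 0.05 was found for 182 genes, a smaller share than the 0.05 that unchanged genes give on average, though the fit leaves out the pairing of repeats.

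In all, 37 of 9630 genes were called against the control ODN at 4 h and all 37 rose, 30 of them by at least 1 on the log2 scale. An unadjusted p below 0.05 was found for 305, a smaller share than the 0.05 that unchanged genes give on average, though the fit leaves out the pairing of repeats. Against medium 21 genes were called, of which 20 rose and 1 fell, Ccdc97 (-1.36 ± 0.30, adjusted p = 0.0433), chosen after its value was seen. It was not called without any 1 of 7 of the 8 arrays (highest adjusted p = 0.290 without medium replicate 1). Against both controls 19 genes rose. The 22 called genes that the rule names lay above the control ODN mean on all measured CpG ODN arrays, 22 of 22, though the same arrays gave the calls. Independent lists would share 0.0769 of 9625 genes. Simulated unchanged groups gave 0 at most, but they leave out the effects and so yield few calls to overlap. Both comparisons share the CpG ODN arrays, which can add to the overlap. With these arrays divided in the same way, 6 to 10 genes were shared over 6 divisions, with 2 arrays in each comparison instead of 4. Of the 4 genes raised at 2 h, 4 were also called at 4 h. The count of 37 fell to 19 without control ODN replicate 3, to 22 without CpG ODN replicate 3 and to 9 with only the compared groups in the fit, and rose to 75 with array weights. Against medium it was 33 with the repeat number as a block within each time, 5 with only the compared groups, 84 with array weights and 12 without the early arrays. Against both controls it was 12 without the early arrays, 5 with only the compared groups and 48 with array weights.

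Of 31 cytokines 5 rose at 4 h, 6 when adjusted over the list alone (list adjusted p = 2.00e-16, and 4.37e-12 with an estimated correlation). Of 34 genes of TLR and NF-kB signalling 6 rose, 11 when adjusted over the list alone, among them Nfkbiz and Nfkbia, the inhibitor of NF-kB (1.21 ± 0.23); the list adjusted p was 7.18e-15, and 6.75e-05 with an estimated correlation. Of 42 interferon response genes 4 rose, 16 when adjusted over the list alone, with Trim30a at 1.24 ± 0.23 and Ifi47 at 1.14 ± 0.22; the list adjusted p was 1.38e-24, and 1.50e-11 with an estimated correlation. Of 35 genes of lymphocyte activation 1 rose, Batf, and 7 when adjusted over the list alone (list adjusted p = 1.47e-07, and 0.0045 with an estimated correlation). Against medium it was 9.54e-04, but adjusted p = 0.130 with an estimated correlation, with 1 gene higher, also 1 when adjusted over the list alone. Nfkbia lost its call without control ODN replicate 3 (adjusted p = 0.059).

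Of 27 chemokines 3 rose, 4 when adjusted over the list alone, and of 31 immediate early genes 4 rose, 5 when adjusted over the list alone. Their list adjusted p was 2.57e-07 and 2.43e-07, and adjusted p = 0.075 and 0.070 with an estimated correlation. Gadd45b, a stress-response gene, rose by 1.12 ± 0.20 and Myc by 1.22 ± 0.25, though the Myc call was lost without each of control ODN replicates 1, 2 and 3 and CpG ODN replicates 3 and 4 (highest adjusted p = 0.100). Among cytokine signalling genes 2 of 37 rose, 3 when adjusted over the list alone, including the suppressor Socs1 at 1.37 ± 0.27 (adjusted p = 0.054 without CpG ODN replicate 3); the list adjusted p was 5.21e-05, and adjusted p = 0.183 with an estimated correlation. The 51 genes of ribosome biogenesis had a median of 0.26 with 0 called by limma and 6 at an unadjusted p below 0.05 (list adjusted p = 7.56e-08, and adjusted p = 0.440 with an estimated correlation). NK cell markers were higher as a group, with 0 of 10 called by limma, 0 at an unadjusted p below 0.05 and a median of 0.27 (list adjusted p = 0.047, and adjusted p = 0.087 with an estimated correlation). Against medium they did not differ by this test (median 0.01, mean -0.07, list adjusted p = 0.990), and the control ODN lay below medium (median -0.44). The other 8 lists passed against medium at 4 h as well. With an estimated correlation 3 did, namely cytokines, TLR and NF-kB signalling and interferon response. Cd69 differed by 1.36 ± 0.37 without passing the test (adjusted p = 0.191), though it passed with array weights. Median, mean and test differed in sign for B cell, monocyte, dendritic cell, platelet and reference tissue markers at 4 h, none of which passed.

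**Figure D1:**
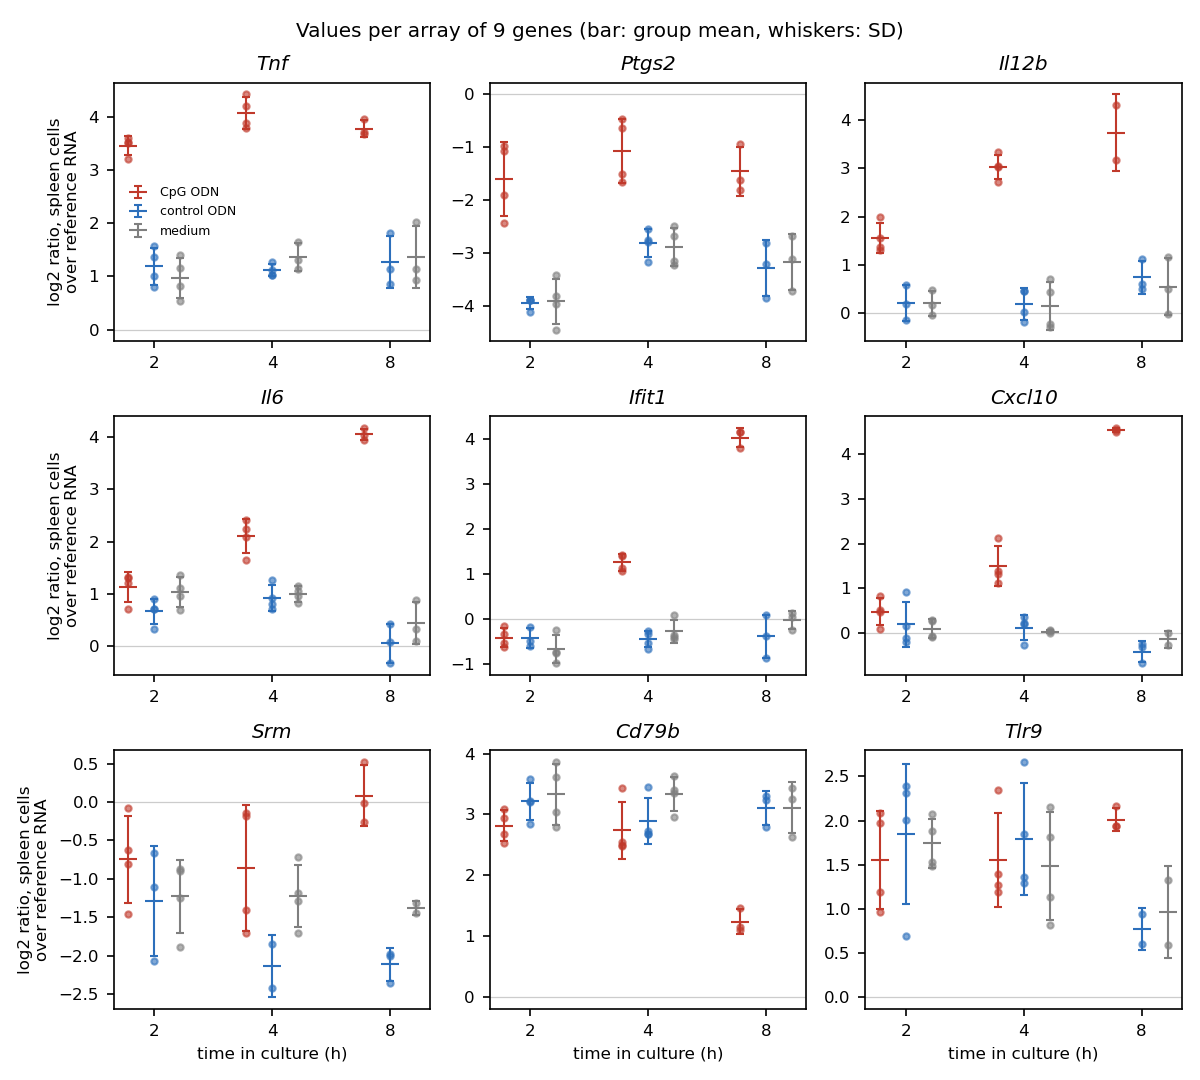
Log2 ratios of 9 genes (vertical axis, spleen cells over reference) against time in culture in h (horizontal axis), with a point per array, a bar for the group mean and whiskers for the SD; CpG ODN is red, control ODN blue and medium grey. Tnf was higher with CpG ODN from 2 h on, by 2.28, 2.96 and 2.51 against the control ODN, while Il6 went from 0.47 at 2 h to 4.00 at 8 h and Cd79b differed by -1.87 at 8 h.

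After 8 h, the largest rises with CpG ODN were mostly of interferon-inducible genes. Cxcl10 exceeded the control ODN by 4.96 ± 0.26 (SE, log2, n = 3 against 3), Ifit3 by 4.75 ± 0.32, the chemokine Cxcl11 by 4.68 ± 0.21 and Ifit1 by 4.43 ± 0.23. Il6 rose by 4.00 ± 0.24, Cmpk2 by 3.89 ± 0.37, the guanylate-binding protein gene Gbp2 by 3.79 ± 0.25, Socs1 by 3.79 ± 0.31 and the nucleic acid sensor Zbp1 by 3.53 ± 0.21. The falls reached -3.68 ± 0.81 for Crisp3 (-2.21 without CpG ODN replicate 2, adjusted p = 0.0416), -2.74 ± 0.30 for Ephx1, the microsomal epoxide hydrolase, -2.18 ± 0.38 for the B cell gene Fcrla and -2.01 ± 0.31 for Rgs2, a regulator of G protein signalling. Against medium, Cxcl10 was at 4.68 ± 0.29 (n = 3 against 2), Il6 at 3.61 ± 0.24, Ephx1 at -2.56 ± 0.30 and Fcrla at -2.34 ± 0.38. The rule for the largest rises and falls required calls of the same sign against both controls, so their shared direction was fixed.

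Of 9494 genes tested, 949 were called against the control ODN at 8 h; 432 rose and 517 fell, and 2104 had an unadjusted p below 0.05. Rises of at least 1 on the log2 scale numbered 307, against 193 falls of that size. The 56 called genes that the rule names lay on the called side of the control ODN mean on all measured CpG ODN arrays, 56 of 56. The same arrays gave the calls, so this is no separate support. Against medium 1115 were called, 536 higher and 579 lower. The median difference of all genes was -0.12 against the control ODN and -0.13 against medium, so that small falls are to be read relative to that shift. With quantile normalization, 414 were higher and 212 lower against the control ODN (66.1% higher, against 45.5%), and 494 and 290 against medium (63.0%, against 48.1%). Both controls together called 700 genes of 9425, 353 higher and 347 lower. Independent lists would share 24.5 and 31.7, though the shared CpG ODN arrays break that independence. Simulated unchanged groups gave 0 at most, but they leave out the effects and so yield few calls to overlap. Part of the excess may come from the shared CpG ODN arrays. The count of 949 was 557 without CpG ODN replicate 2, 625 without CpG ODN replicate 3, 627 without control ODN replicate 2 and 564 with only the compared groups in the fit. Against both controls it was 431 without CpG ODN replicate 2 and 277 with only the compared groups, and against medium 690 without CpG ODN replicate 2, 711 without medium replicate 2, 315 with only the compared groups and 1995 with array weights. With the repeat number as a block within each time the counts were 1489 against the control ODN, 1698 against medium and 1081 against both.

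**Figure D2:**
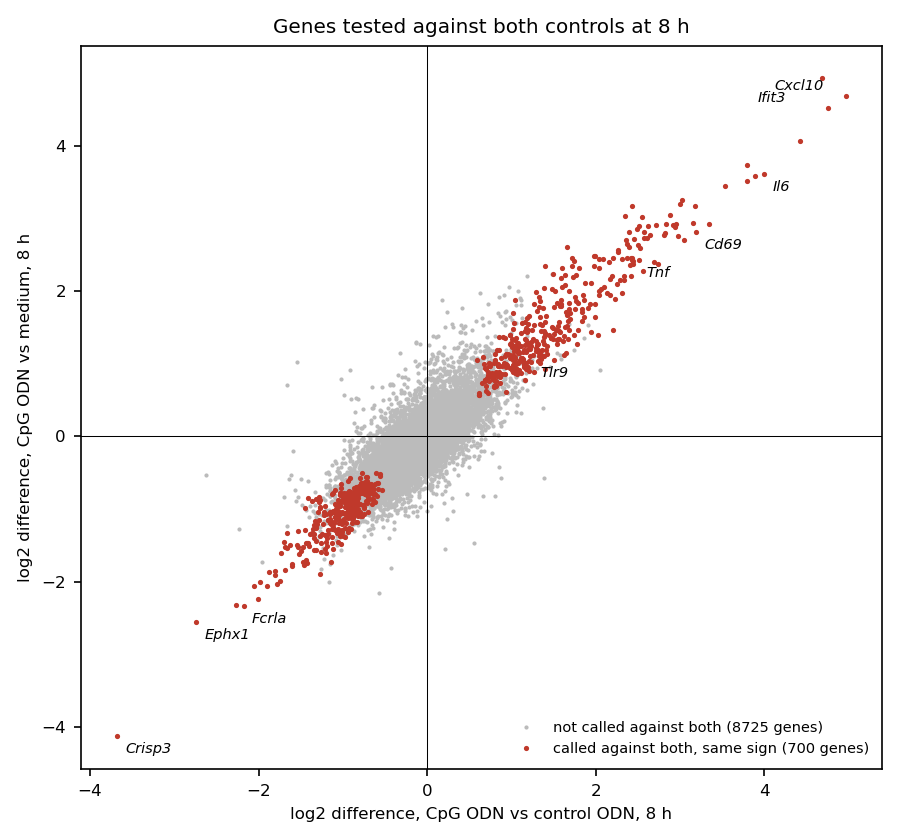
Log2 difference of CpG ODN from control ODN (horizontal axis) and from medium (vertical axis) at 8 h, with a point per gene tested in both; red points are the 700 genes called against both with the same sign and grey points the rest of 9425. Cxcl10 lies at 4.96 and 4.68 and Ephx1 at -2.74 and -2.56.

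The interferon response was the list with the most members called at 8 h. Of 42 genes 29 rose and 0 fell by limma, 31 when adjusted over the list alone, with a median of 1.79 (list adjusted p = 1.56e-71, and 1.43e-33 with an estimated correlation). Of 30 cytokines 8 rose and 2 fell, 12 when adjusted over the list alone, with Il6 in front, Il12b at 3.00 ± 0.36 (n = 2 against 3), Tnf at 2.51 ± 0.27 and Il10, an anti-inflammatory cytokine, at 1.78 ± 0.40; the list adjusted p was 1.18e-05, and 4.92e-04 with an estimated correlation. Ifng, type II interferon, rose by 1.08 ± 0.32 (adjusted p = 0.027), a call lost without control ODN replicate 1 or 2 or CpG ODN replicate 2 or 3 (highest adjusted p = 0.149). Of 26 chemokines 4 rose, 6 when adjusted over the list alone, with Cxcl9 at 2.81 ± 0.27 and Ccl3 at 2.04 ± 0.26, while the list's median was -0.003 against a mean of 0.48 (list adjusted p = 6.96e-07, and adjusted p = 0.085 with an estimated correlation). Ccl4 differed by 0.18 ± 0.21 and was not called.

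Genes of ribosome biogenesis and MYC-driven growth rose at 8 h, 25 of 50 with 0 falling by limma, 26 when adjusted over the list alone. Srm, the spermidine synthase gene, rose by 2.20 ± 0.41 and Atic, of purine synthesis, by 1.74 ± 0.35, and Myc itself by 1.56 ± 0.29. The list's median was 0.78 (list adjusted p = 3.27e-15), but its members move together between arrays, and adjusted p = 0.160 with an estimated correlation. Of 35 genes of TLR and NF-kB signalling 7 rose and 1 fell, 13 when adjusted over the list alone, with the RNA sensor Tlr7 at 2.40 ± 0.24 and Nfkbiz at 2.31 ± 0.22 (list adjusted p = 0.0024, and adjusted p = 0.250 with an estimated correlation). Tlr9 differed by 1.24 ± 0.47 (n = 3 against 2) without passing the test (adjusted p = 0.095), though it passed with the repeat number as a block and with only the compared groups in the fit.

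Of 31 immediate early genes 7 rose and 2 fell, 10 when adjusted over the list alone, with Jun at 2.31 ± 0.24 and Atf3 at 1.98 ± 0.32; the median was -0.07 against a mean of 0.31 (list adjusted p = 0.0025, and adjusted p = 0.401 with an estimated correlation). Among 35 genes of lymphocyte activation 6 rose and 4 fell, 11 when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.071), though it did against medium (0.0447, but adjusted p = 0.448 with an estimated correlation). The early activation marker Cd69 rose by 3.19 ± 0.43 and Slamf1 by 2.26 ± 0.26, whereas Cd86 differed by 0.30 ± 0.36 and was not called. Of 37 cytokine signalling genes 6 rose and 1 fell, 8 when adjusted over the list alone, Socs1 foremost (list adjusted p = 0.053; against medium 0.00201, but adjusted p = 0.363 with an estimated correlation). Of 51 cell cycle genes 5 rose and 2 fell, 8 when adjusted over the list alone, with the cyclin Ccnd2 at 2.42 ± 0.26 and the inhibitor Cdkn2d at 1.73 ± 0.32 (list adjusted p = 0.142). Of 36 apoptosis genes 5 rose and 3 fell, 9 when adjusted over the list alone, with the inhibitor Cflar at 1.56 ± 0.21 (list adjusted p = 0.326). Of 26 heat shock and unfolded protein genes 4 rose and 1 fell, 5 when adjusted over the list alone, the mitochondrial chaperone Hspd1 among the rises and the sensor kinase Eif2ak3 at -1.69 ± 0.34 (list adjusted p = 0.211; against medium 0.0229, but adjusted p = 0.407 with an estimated correlation).

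A few markers of B and T cells fell with CpG ODN against the control ODN at 8 h. Of 15 B cell markers 3 fell and 0 rose, 3 when adjusted over the list alone, with Cd79b, a chain of the B cell receptor, at -1.87 ± 0.29. Of 16 T cell markers 4 fell and 0 rose, 6 when adjusted over the list alone, with the signalling adaptor Lat at -1.20 ± 0.27. The list adjusted p was 0.041 for B cells and 0.013 for T cells, and adjusted p = 0.616 for each with an estimated correlation; against medium it was 0.293 and 0.070. Of 16 genes of MHC class II presentation 1 fell, the peptide-loading gene H2-DMb1 at -1.70 ± 0.25, also 1 when adjusted over the list alone (list adjusted p = 0.134). Of the NK cell markers 2 of 10 were higher by either adjustment (adjusted over the list alone 2), with Tbx21 at 2.36 ± 0.36 and the granzyme Gzmb at 1.83 ± 0.40 (list adjusted p = 0.034, and adjusted p = 0.068 with an estimated correlation). Against medium the list did not pass (adjusted p = 0.189, and 0.337 with an estimated correlation). In all 9 lists passed against medium at 8 h, the 6 functional lists that passed against the control ODN and those of lymphocyte activation, cytokine signalling and heat shock, but only cytokines and interferon response with an estimated correlation (adjusted p = 2.18e-04 and 9.64e-31).

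The remaining cell type lists did not pass at 8 h. Of 6 other cell types, only erythroid markers lay below the median of all genes by more than 2 SE, and NK cell markers lay above it at 0.74 ± 0.08. Less the median of all genes, erythroid markers differed from the control ODN by a mean of -0.28 ± 0.02 (SE). Neutrophil markers were at -0.41 ± 0.25, macrophage markers at -0.32 ± 0.19, platelet markers at -0.12 ± 0.15 and dendritic cell markers at -0.0046 ± 0.039, each within 2 SE of 0. Among 14 monocyte and macrophage markers 1 rose and 2 fell, 5 when adjusted over the list alone, with Vcam1 at -1.01 ± 0.24 (list adjusted p = 0.189). Vcam1 was at -0.75 and did not pass with quantile normalization. Of 8 dendritic cell markers and of 11 markers of neutrophils 0 were called by limma or when adjusted over the list alone, with 0 and 1 at an unadjusted p below 0.05 (list adjusted p = 0.937 and 0.493). Of 11 erythroid markers 1 fell, 1 when adjusted over the list alone (list adjusted p = 0.473), and of 7 platelet markers 1 fell, 1 when adjusted over the list alone (list adjusted p = 0.698). The platelet call, Gp9, was lost in the limma fit without any 1 of the 6 arrays (highest adjusted p = 0.141). The erythroid call, Epb42, was lost without control ODN replicate 3 (adjusted p = 0.052). The 20 markers of non-splenic tissues, which report on the reference channel, had 0 calls by limma and 0 at an unadjusted p below 0.05 (list adjusted p = 0.778).

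**Figure D3:**
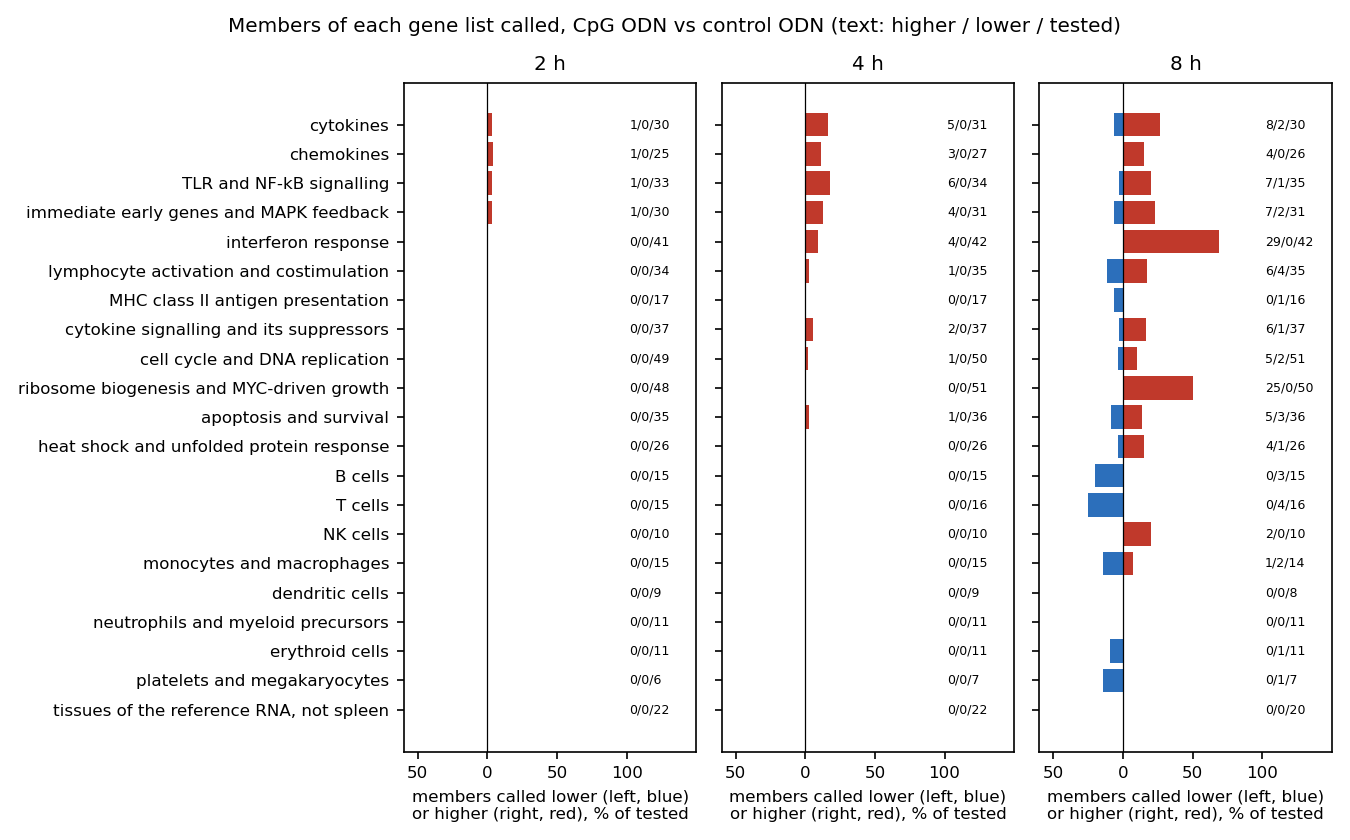
Share of the tested members of each gene list called higher (bars to the right) or lower (bars to the left) with CpG ODN than with control ODN, in % of members tested, at 2, 4 and 8 h; the text in each row gives members higher, lower and tested. At 8 h, 29 of 42 interferon response genes and 25 of 50 ribosome biogenesis genes were higher, while 3 of 15 B cell and 4 of 16 T cell markers were lower.

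The difference between CpG ODN and control ODN itself changed from 2 h to 8 h in 298 of 9141 genes, upward in 195 and downward in 103. The largest changes belonged to Cxcl10 (4.68 ± 0.34), Ifit3 (4.50 ± 0.43), Cxcl11 (4.45 ± 0.29), Ifit1 (4.41 ± 0.31) and Socs1 (3.88 ± 0.41), all with limma adjusted p of 1.66e-07 or lower. Crisp3 (-3.96 ± 1.11), Ephx1 (-2.74 ± 0.39), Jhy (-2.31 ± 0.53), the endothelial and myeloid surface gene Cd93 (-2.01 ± 0.44) and the lipopolysaccharide co-receptor Cd14 (-1.97 ± 0.40) moved downward. Crisp3 was not called without any 1 of 9 of the 14 arrays, and was at -2.49 without CpG ODN 8 h replicate 2 (adjusted p = 0.160). All 4 genes raised at 2 h were also called higher at 8 h, as were 30 of the 37 raised at 4 h. With quantile normalization 189 moved upward and 45 downward (80.8% upward, against 65.4%). With array weights the count was 473, and with the repeat number as a block within each time 524.

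Few single genes, if any, were called between the control ODN and medium. With limma, 0 genes were called at 2 h among 9239, at 4 h among 9637 and at 8 h among 9526. An unadjusted p below 0.05 was found for 229, 176 and 379. Each is a smaller share than the 0.05 that unchanged genes give on average. The fit leaves out the pairing of repeats, which can make p-values too large, so these shares do not show that nothing changed. The 2 h count was 2 without medium replicate 1, the 4 h count 1 with only the compared groups in the fit, and the 8 h count 1 without medium replicate 1. At 8 h, where repeat numbers pair the arrays, the fit with the repeat number as a block called 1 gene, Dqx1 (-1.95 ± 0.28, adjusted p = 0.025), chosen after its value was seen. As groups, ribosome biogenesis genes were lower at 2 h (median -0.08, list adjusted p = 0.021, and adjusted p = 0.784 with an estimated correlation) and cytokine signalling genes higher at 8 h (median 0.15, list adjusted p = 0.021, and adjusted p = 0.521 with an estimated correlation). The heat shock list was lower at 2 h and 4 h (medians -0.08 and -0.19, list adjusted p = 0.047 and 0.042) and higher at 8 h (median 0.10, list adjusted p = 0.042), with adjusted p = 0.456, 0.448 and 0.448 with an estimated correlation. NK cell markers were lower at 4 h (median -0.44, list adjusted p = 0.018, and 0.037 with an estimated correlation). By limma 0 members of these lists were called, with 3, 4, 1, 1, 4 and 0 at an unadjusted p below 0.05 in the order given.

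Culture in medium alone changed many genes between 2 h and 8 h. The transglutaminase gene Tgm2 fell by 4.04 ± 1.10 (SE, log2, n = 2 against 4), and C1qb, of the complement C1q complex, by 3.21 ± 0.24 (n = 3 against 3). Of 15 monocyte and macrophage markers 1 rose and 3 fell, 5 when adjusted over the list alone, among them Vcam1 (-2.59 ± 0.23) and Fcgr3 (1.14 ± 0.35), both chosen after their values were seen. The Fcgr3 call was lost without any 1 of 4 of the 7 arrays, with 0.74 without medium 8 h replicate 3 (adjusted p = 0.239) and 1.73 without medium 8 h replicate 1. The largest rises belonged to Atp2b2 (2.98 ± 0.59), Arhgef25 (2.91 ± 0.73), Ak8 (2.75 ± 0.75), Wtap (2.70 ± 0.39) and Hnrnpll (2.66 ± 0.38), the last of these a splicing regulator of lymphocytes. Without medium 8 h replicate 3, Arhgef25 and Ak8 were not called (2.23 and 2.13, adjusted p = 0.0802 and 0.107). With limma, 1379 of 9475 genes were called, 877 higher and 502 lower at 8 h; 2577 had an unadjusted p below 0.05. Of 31 immediate early genes 7 fell and 0 rose, 7 when adjusted over the list alone, and of 48 cell cycle genes 12 fell and 3 rose, 15 when adjusted over the list alone. Of 15 B cell markers 0 were called by limma, with 1 at an unadjusted p below 0.05. The count was 779 without medium 8 h replicate 3, 385 with only the compared groups in the fit and 2704 with array weights.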

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

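The tests of other splits of the arrays, of fewer B and T cells and of the macrophage genes were chosen after the results were seen. The rule for which list members enter the tests of ratio compression was also settled after a first look.

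In groups of 4 arrays, 80 tests looked for an array far from the other 3, and chance picks about 1 in 20 groups. The arrays listed here are no more than chance picks at that rate. Ptgs2 with the control ODN at 2 h was at -4.12 in replicate 4, against -3.90 to -3.89 in the others. Ifit1 in medium at 4 h was at 0.0924 in replicate 2, against -0.45 to -0.36. Myc with the control ODN at 4 h was at 0.78 in replicate 4, against 0.00 to 0.04. Gadd45b with CpG ODN at 4 h was at 1.75 in replicate 2, against 1.47 to 1.49.

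The difference between CpG ODN and control ODN changed between times by a limma test of that change. From 2 h to 4 h it changed for 1 gene, Ifit1 (1.69), and 0 genes were called without any 1 of 7 of the 16 arrays compared. From 2 h to 8 h it changed for 298 genes, with the largest changes for Cxcl10 (4.68), Ifit3 (4.50), Cxcl11 (4.45), Ifit1 (4.41) and Socs1 (3.88) upward and Crisp3 (-3.96, but -2.49 and not called without CpG ODN 8 h replicate 2), Ephx1 (-2.74), Jhy (-2.31), Cd93 (-2.01) and Cd14 (-1.97) downward.

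Markers of B and T cells were lower with CpG ODN than with the control ODN at 8 h, by a mean of -0.70 ± 0.15 (SE) over 31 genes. The median of all genes (-0.12) is not subtracted in this mean, whereas it is in the values of the other types below. Neither list passed against medium and both lost their call with an estimated correlation (adjusted p = 0.616 for each). Fewer B and T cells would raise the markers of every other type alike only if nothing else changed those markers. Of 6 other types 1 lay below the median of all genes by more than 2 SE, erythroid cells at -0.28 ± 0.02, while NK cell markers lay at 0.74 ± 0.08. Neutrophil markers (-0.41 ± 0.25) and macrophage markers (-0.32 ± 0.19) lay lower too, within 2 SE. This form of the test followed a pooled mean of 61 markers that decided nothing (-0.10 ± 0.10) and a count of 4 types with the array medians subtracted. It rests on 1 type, and regulation of markers cannot be told here from cell number. The test therefore cannot decide on fewer B and T cells, which stays open. Genes matched on their ratio to the reference also fell (-0.43 ± 0.10). The markers lay below them by -0.26 ± 0.13, a narrow margin (-0.31 ± 0.12 for 24 markers on all 6 arrays). The median ratio of the markers in medium at 4 h was 2.39, so the matched genes are themselves high in spleen cells over the reference. Fewer or altered spleen cells could lower them too, so the match cannot tell ratio compression from such a change. With quantile normalization the markers stayed at -0.58 ± 0.12. A lower level of these transcripts per cell remains an open biological hypothesis, untested here.

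Macrophage genes were lower in medium at 8 h than at 2 h for 3 of 15 markers, C1qb, Vcam1 and C1qc, with a mean of -2.48 ± 0.12. If a loss of macrophages lowered all 15 by about as much, their median would lie at or below the smallest of the 3 falls, -1.81 for C1qc. It was -0.43 (SD 1.15), above that fall by more than the SD, so the 15 did not fall alike. Most of the others also lay below 0, such as Spic (-0.53 ± 0.28), Adgre1 (-0.46 ± 0.31) and Cd68 (-0.42 ± 0.28), while Cd163 and Fcgr3 lay above 0. Since the 3 falls were picked from these data, the median was near certain to lie above them. The test cannot decide on a loss of macrophages, which stays open. This form followed 2 others, the gap between the other 12 markers and the 3 picked for falling (2.31 ± 0.20) and the mean of all 15 (-0.62 ± 0.13), which the 3 largely set. A change of these genes within macrophages in culture may be stated only as a hypothesis, untested here.

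Ribosome biogenesis genes were higher with CpG ODN than with the control ODN at 8 h by a mean of 0.73 ± 0.13 over 50 genes. Genes matched on their ratio to the reference were at -0.02 ± 0.03, and the list lay above them by 0.75 ± 0.12 (0.83 ± 0.14 for 43 genes on all 6 arrays), which argues against ratio compression as the cause. With quantile normalization the mean was 0.74 ± 0.12, and the lowest on leaving out 1 of the 6 arrays was 0.67 ± 0.18. Induction of growth genes by CpG ODN is a hypothesis consistent with these values; the list's own test was lost with an estimated correlation.

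Other splits of the same arrays were counted for each comparison, the real one included. At 2 h, 2 of 35 splits gave as many genes as CpG ODN against control ODN (4 real, highest other 5) and 3 of 35 as many as against medium (4 real, highest other 4), so chance is not excluded for the counts. Of the 8 splits that part all pairs of repeat numbers, as the real one does, the highest other gave 0 against the control ODN and 2 against medium. The pairing is partial, so this does not settle it. For both controls together 3 of 100 did (4 real, highest other 11), a share under 0.05. At 4 h, 1 of 35 splits, the real one, gave 37 genes against the control ODN (highest other 1) and 1 of 35 gave 21 against medium (highest other 2). Against both, 1 of 100 gave 19 (highest other 0), and each share lies under 0.05. The share of 1 of 35 is the lowest that 35 splits can give. Splits that mix CpG ODN and control arrays carry the CpG ODN effect in the spread within groups, which can lower their counts. By itself this count cannot exclude chance. At 8 h the 10 splits are too few for a share under 0.05; 1 of 10 gave 949 against the control ODN (highest other 23) and 1 of 10 gave 1115 against medium (highest other 2). For both controls at 8 h it was 1 of 100 (700 real, highest other 196).

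For control ODN against medium the real count was 0 at each time by limma, so 35 of 35 splits at 2 h, 35 of 35 at 4 h and 10 of 10 at 8 h gave as many. There 229, 176 and 379 genes had an unadjusted p below 0.05, each a smaller share than unchanged genes give on average, in a fit without the pairing. The highest other was 60 at 2 h, 1 at 4 h and 165 at 8 h. The 60 and the 165 point to a structure of the samples. The 165 came from control ODN replicate 2 with medium replicates 2 and 3 against the rest; of the 4 splits that part all 3 pairs, as the real one does, the highest other gave 0, and the blocked fit called 1. At 2 h, splits with both early arrays on 1 side reached 41 at most. For medium at 8 h against 2 h it was 1 of 35 (1379 real, highest other 629, with medium 2 h replicates 2, 3 and 4 on 1 side). For the change from 2 h to 4 h, 4 of 100 splits gave at least the 1 real gene, and the highest other, 451, points to a structure of the samples. For the change from 2 h to 8 h, 12 of 100 gave at least 298 (highest other 551), all 12 among the 13 that keep the real 8 h groups; the other splits gave 4 at most.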

How the results depend on the processing

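The test that added the unnamed probes was chosen after the data were seen; it called 0, 2 and 75 of them against the control ODN at 2, 4 and 8 h and moved no count by over 1.5 times. Of 82 called values of named genes, 1500 of 1603 alternative values passed with the same direction, 103 kept the direction without passing and 0 turned. Of 647 alternative values for 32 named values not called, 5 passed and 17 turned. The cause of the changes below was not tested, except that fits with only the compared groups have fewer arrays to estimate the spread. Signal over background is not in the table, so its limit is unknown.

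With quantile normalization, CpG ODN against medium called 8 genes at 2 h and against the control ODN 626 at 8 h. With the repeat number as a block within each time, CpG ODN against medium called 7, 33 and 1698 at 2, 4 and 8 h, against the control ODN 1489 and against both 1081 at 8 h, control ODN against medium 1 at 8 h, and the change from 2 h to 8 h 524. The repeat numbers paired 21 of 33 pairs above a correlation of 0.1 (median 0.36, -0.41 to 0.74), and 18 of 33 correlated best with their own number. With only the compared groups, counts at 4 h were 9 against the control ODN, 5 against medium, 5 against both and 1 for control ODN against medium; at 8 h they were 564, 315 and 277, and 385 for medium over time. With array weights, CpG ODN against medium gave 122, 84 and 1995 at 2, 4 and 8 h, against the control ODN 75 and both 48 at 4 h, the changes between times 11 and 473, and medium over time 2704. Without the early arrays, 4 h gave 12 against medium and 12 against both. The change from 2 h to 4 h gave 0 without the early arrays, with genes measured on every array and with a block shared across times. With an estimated correlation 1, 4 and 2 lists passed at 2, 4 and 8 h.

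Leaving out 1 array gave, against the control ODN, 4 to 5 genes at 2 h, 19 to 39 at 4 h and 557 to 887 at 8 h. Against medium it gave 4 to 11, 16 to 24 and 690 to 1415, and against both 4 to 4, 15 to 24 and 431 to 686. Control ODN against medium gave 0 to 2, 0 to 0 and 0 to 1, the changes between times 0 to 2 and 201 to 324, and medium over time 779 to 1601. Lists numbered 5 to 9, 8 to 11 and 9 to 10.

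Values not called that turned sign were close to 0. At 2 h, Socs3 was at -0.00592 without centring and -0.13 to 0.11 on leaving out 1 array (-0.01, -0.13, -0.10 and -0.03 without control ODN replicates 1 and 4 and CpG ODN replicates 2 and 3). Cd86 at 2 h was at -0.19 with array weights and -0.20 to 0.22 on leaving out 1 array (-0.00396, -0.06, -0.03 and -0.20 without CpG ODN replicate 1, control ODN replicates 2 and 4 and CpG ODN replicate 4). Il10 ranged from -0.53 to 0.15 and Ccl4 from -0.0608 to 0.16 at 2 h. At 4 h, Tlr9 ranged from -0.50 to 0.0509, Ifng from -0.0791 to 0.30 (-0.06 without CpG ODN replicate 3) and Cd86 from -0.15 to 0.33 (-0.00694 without control ODN replicate 3).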

Other observations

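The thresholds behind this set of genes were chosen after the data were seen, and no test of a hypothesis was run on it. At 8 h, 71 genes were at least 2 higher on the log2 scale with CpG ODN than with both controls, and 17 of these were within 0.3 of the control ODN at 4 h. Among the 17 were Ly6f (3.35 ± 0.40, SE, n = 3 against 3), the complement factor gene Cfb (2.88 ± 0.31), the antiviral kinase gene Eif2ak2 (2.58 ± 0.32), the zinc finger gene Zbtb32 (2.37 ± 0.30), Tbx21, a transcription factor of type 1 lymphocyte responses (2.36 ± 0.36), and the interferon-inducible membrane gene Ifitm3 (2.29 ± 0.28). Others were Zc2hc1c (2.64), Slx4ip (2.45), Tchhl1 (2.37) and Mov10 (2.35). The SE at 4 h ran from 0.19 for Wdr36 to 0.35 for Ly6f, so a small rise before 8 h cannot be excluded. Of 1017 probes without a gene symbol, 75 were called at 8 h against the control ODN, 35 of them higher.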
